A study of Mus musculus with 2 samples.

How the data were processed

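Chromatin carrying histone H3 dimethylated at lysine 4 (H3K4me2) was immunoprecipitated and sequenced from embryonic facial prominences of B6NCrl mice at embryonic day 11.5. Per the labels, replicate 1 came from a pool of 109 embryos and replicate 2 from a pool of 88 embryos, both sexes mixed, with library fragments of 300 to 500 bp. The labels name both libraries as biological replicates, so 1 group of n = 2 was available and no contrast between conditions could be made.

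The deposited data were 4 peak lists on mm10 (GRCm38): a list called on each replicate alone, a list called on both replicates pooled, and a list of replicated peaks. Per the file lists deposited with the samples, the replicated list was derived from the pooled list and both own lists. The same file lists name 2 further inputs behind the list of replicate 1 and 1 behind that of replicate 2, without stating their role. The aligner, the peak caller, its threshold and the replication criterion are not given in the sources used here. The signal value of each peak is an enrichment that the authors deposited, and its scaling is not stated. It was ranked and summarised only within its own list. The −log10 p-value and −log10 q-value of each peak were deposited by the authors and served to rank and filter peaks within a list. The deposited display score of each peak was not used. The lowest −log10 p-value was 2.02 in the list of replicate 1, 2.0 in that of replicate 2 and 2.05 in the pooled list. The files hold no read counts, so the sequencing depth of each library is unknown, and no interval that needs read numbers was computed.

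Gene positions came from GENCODE M21 on GRCm38, with 21938 protein-coding genes and 93513 start sites, taking every transcript start of these genes. Peaks on all 21 chromosomes ended within the lengths of the reference sequences. Coordinates are 1-based. A gene was called marked when a peak lay within 1000 bp of any of its starts. Breadth was the number of base pairs covered by peaks within 5000 bp either side of the gene's most covered start. A distal peak lay over 2500 bp from every protein-coding start and was assigned to the gene of the nearest start within 100000 bp. Domains were replicated peaks merged across gaps of up to 1000 bp. CpG counts were taken within 500 bp of each gene's 5′-most start. Random lists matched on CpG count drew each gene from the member's bin, out of 10 bins of that count.

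Replicate lists were compared by the share of peaks overlapping a peak of the other list by at least 0.5 of the shorter peak, and by the Jaccard index of covered base pairs. The other list was placed 100 times at random on the same chromosomes, outside assembly gaps of at least 1000 bases. The smallest permutation p these placements can give is 0.0099 one-sided and 0.0198 two-sided. Gene lists were compared with the other protein-coding genes by Fisher's exact test for promoter marking and for membership of the 500 widest domains. Breadth and distal peaks were compared with 10000 random lists of equal size, for which the smallest two-sided permutation p is 0.0002. All list tests were two-sided and adjusted by the Benjamini-Hochberg method over the 18 lists of each measure, with calls at an adjusted p under 0.05. These p-values treat genes as units and describe the peaks of this tissue. Neighbouring genes can share peaks, so p-values for clustered genes such as Hox genes and olfactory receptors are too small. They do not measure variation between embryos. The mean and SD over the own lists describe the difference between 2 pooled libraries, which can include differences in depth.

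The 18 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists were regulators of cranial neural crest and facial mesenchyme (25 genes), jaw and arch patterning (21), facial epithelium (22), signalling in facial outgrowth (28), cartilage and bone (21), nervous system and sensory placodes (23), pigment and glial crest derivatives (16), skeletal muscle (22), endothelium (20), erythroid and myeloid blood (20), lymphocytes (20), Hox genes (39), heart (20), liver (21), germ cells (20), pluripotency (20), housekeeping (20) and olfactory receptors (1135). No gene belonged to more than 1 list, and every member was found in the annotation. Always named were Tfap2a, Twist1, Msx1, Dlx5, Alx4, Sox9, Irf6, Trp63, Shh, Hand2, Hoxa2 and Alb. The rule also named the 2 members of each list with the greatest breadth and the first 2 members lacking a replicated promoter peak. It further named genes at the 10 widest domains, the 5 genes with the most distal peaks and the gene nearest each of the 5 most enriched peaks. Other genes are named where stated as chosen after their values were seen.

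Alternatives covered stricter q-values, other overlap rules, lists cut to equal length, pooled peaks, each own list alone, other promoter, breadth and distal windows, other merging gaps and random lists matched on CpG count or on the length of sequence nearest to a gene. Alternatives with replicated peaks found in both own lists, and with distal peaks outside merged domains that reached within 2500 bp of a start, were added after the data were examined. The list tests were tested on simulated lists for the same 21938 genes: 9 of 10 changed lists were called for promoter marking and 10 of 10 for breadth, distal peaks and widest domains. Of 40 unchanged lists, 1 was called for promoter marking and 0 for the other measures. The planted changes were large and the lists were random genes. Outside the changed lists, promoter peaks were simulated for a smaller share of genes than was marked in the data. These counts therefore do not give the power for smaller effects or at the share marked in the data, or the false calls for clustered or CpG-rich genes. All 5 counts of overlaps, merged intervals and nearest distances computed in parallel with bedtools 2.31.1 were equal. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Peaks on unplaced contigs were left out of tests that use genes or random placement.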

Results

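H3K4me2, a histone mark found at promoters and enhancers, was mapped in the facial prominences of mouse embryos at embryonic day 11.5. These prominences are buds of neural crest mesenchyme covered by ectoderm that grow and fuse to form the face. Genes of facial mesenchyme, such as Six2, Msx1 and Twist1, lay in broad H3K4me2 domains, whereas Alb and the other liver genes examined had no replicated promoter peak. The samples were 2 biological replicates, pools of 109 and 88 embryos. Replicate 1 had 49058 peaks covering 36.9 Mb with a median width of 406 bp, and replicate 2 had 36883 peaks covering 27.5 Mb with a median width of 542 bp. The number of peaks per replicate was 42970.5 ± 8609 (mean ± SD, n = 2). The pooled list had 35021 peaks and the replicated list 31263 peaks covering 32.0 Mb, with a median width of 824 bp. Chromosome X carried 969 replicated peaks and chromosome Y 2. Read depth is unknown because the files hold no read counts.

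The first comparison asked how far the marked regions of the replicates coincided. Promoters of Tfap2a, Twist1, Msx1, Dlx5, Alx4, Sox9, Irf6, Shh, Hand2 and Hoxa2 were marked in both own lists. Trp63, a gene of the ectoderm, had a promoter peak in replicate 1 and none in replicate 2, and Hand1, Myf5, Nkx2-5, Hoxa3 and Dcx followed the same pattern. Sycp1, a meiotic gene, was marked in replicate 2 alone. Across all protein-coding genes, 14272 were marked in both own lists, 477 in replicate 1 alone and 62 in replicate 2 alone.

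Of the peaks of replicate 1, 26639 (54.3%) overlapped a peak of replicate 2, against 1.69% for randomly placed peaks. Of the peaks of replicate 2, 31474 (85.3%) overlapped a peak of replicate 1, against 2.25% for placed peaks. The Jaccard index of covered base pairs was 0.657, against 0.00675 for placed peaks. Each comparison gave a one-sided permutation p of 0.0099, the smallest that 100 placements can give. Every peak in the strongest 3 deciles of either list was shared, and the share declined to 5.52% in the weakest decile of replicate 1 and to 44.2% in the weakest decile of replicate 2. Shared peaks of replicate 1 had a median width of 991 bp and lay at promoters in 71.0% of cases, whereas its 22419 unshared peaks had a median width of 209 bp and lay at promoters in 20.1%. The 5409 unshared peaks of replicate 2 had a median width of 195 bp and lay at promoters in 19.9%. For 20689 peaks with a single partner, Spearman's correlation between replicates, across peaks that are not independent, was 0.888 for enrichment rank and 0.920 for width.

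**Figure D1:**
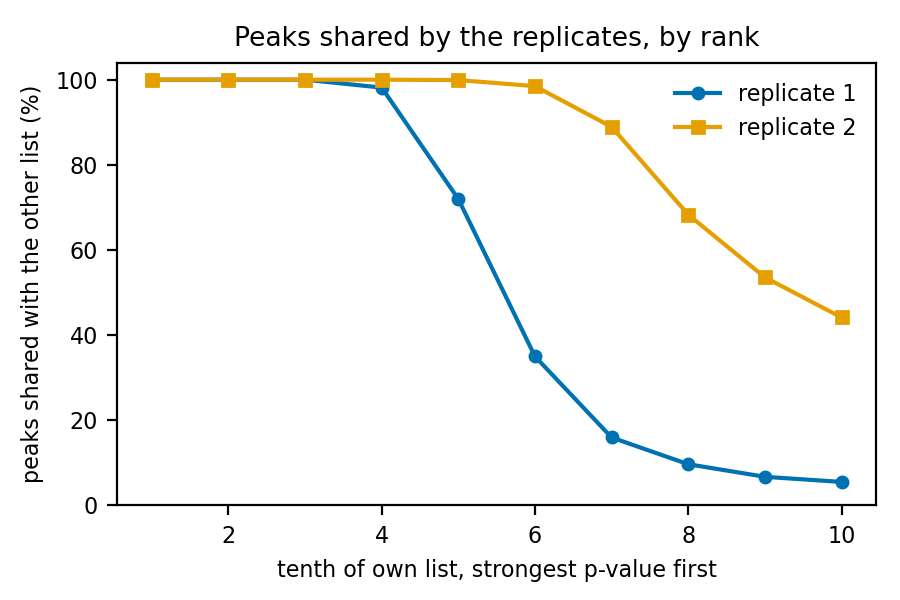
Share of peaks (%) overlapping a peak of the other replicate (vertical axis) for each decile of a replicate's own list, strongest p-value first (horizontal axis), with 1 point per decile. Sharing is complete in the first 3 deciles of both lists and declines to 5.52% in replicate 1 and 44.2% in replicate 2.

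The second comparison asked which pooled peaks were also called replicated. Pooled peaks at the promoters of Hand1 and Nkx2-5, regulators of jaw and heart, were absent from the replicated list. Of the 35021 pooled peaks, 31263 (89.3%) were also in the replicated list. These had a median enrichment of 9.34 and a median width of 824 bp, and 64.4% lay at promoters. The other 3758 had a median enrichment of 3.18 and a median width of 199 bp, and 25.1% lay at promoters. Of the replicated peaks, 26703 (85.4%) overlapped a peak of both own lists, 3856 (12.3%) of replicate 1 alone, 519 (1.66%) of replicate 2 alone and 185 (0.592%) of neither.

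The third comparison asked where the mark lay in the genome. The most enriched replicated peaks lay at the starts of Egr1, Cited4, Cabp1, Rasgef1c and Specc1, with enrichment values of 48.2, 47.8, 47.5, 46.7 and 46.0. Egr1, an immediate-early transcription factor gene, carried its peak at chromosome 18, 34859415 to 34863228. Promoters held 20136 (64.4%) of the replicated peaks and 80.0% of their base pairs. The own lists gave 47.8% and 62.4% (55.1 ± 10.4, mean ± SD, n = 2), and placed peaks gave 5.81%, so that promoters held 11.1-fold more peaks than placement (two-sided permutation p = 0.0198, the smallest possible). Exons outside promoters held 4.71% of peaks, introns 12% and intergenic sequence 18.9%, each below placement (6.87%, 30.3% and 57.0%, permutation p = 0.0198 each). Each peak was counted in a single class, so the excess at promoters by itself lowers the other shares. These lower shares are therefore no separate evidence of depletion. The 8811 peaks over 2.5 kb from every protein-coding start (28.2%) had a median width of 452 bp, against 1100 bp at promoters. A replicated promoter peak was present at 14419 of 21938 protein-coding genes (65.7%). The own lists marked 66.3 ± 1.34% of genes (mean ± SD, n = 2).

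The fourth comparison asked which gene programmes were marked at their promoters. All 25 regulators of cranial neural crest and facial mesenchyme, among them Tfap2a, Twist1, Msx1, Alx4 and Sox9, carried a replicated promoter peak, as did all 28 signalling genes of facial outgrowth, among them Shh, Ptch1 and Wnt5a. Of the jaw and arch genes, 20 of 21 (95.2%) were marked, Hand1 being the exception. At the other extreme, 0 of 21 liver genes were marked, Alb, Apoa1 and Apoa2 included, a count whose exact 95% binomial interval reaches 16.1%. In the own list of replicate 2 the share was 4.76%. Olfactory receptor genes were marked in 2 of 1135 cases (0.176%), 1 of them Olfr94, while Olfr95, Olfr1415 and Olfr1416 were not; the own list of replicate 1 marked 0.352%. Against 65.7% to 69.3% of the remaining genes, the adjusted Fisher's exact p was 0.000156 for neural crest, 4.43e-05 for signalling, 0.00467 for jaw and arch and 1.52e-09 for liver. The p for olfactory receptors was too small for double precision.

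Housekeeping genes were marked in 20 of 20 cases, Tubb5 and Polr2a included (adjusted Fisher's exact p = 0.00104), and nervous system and placode genes in 21 of 23 (91.3%, adjusted exact p = 0.0125), with Dcx and Phox2b unmarked. Lymphocyte genes were marked in 2 of 20 cases (10%, adjusted exact p = 2.19e-06), with Lck marked and Cd3e, Cd3d and Rag2 unmarked. Germ cell genes were marked in 4 of 20 (20%, adjusted exact p = 0.000133), with Tdrd1 marked and Ddx4, Sycp1 and Tnp2 unmarked. Blood genes were marked in 5 of 20 (25%, adjusted exact p = 0.000609), with Runx1 marked and Gata1, Hba-a1 and Cd68 unmarked. Skeletal muscle genes were marked in 8 of 22 (36.4%, adjusted exact p = 0.0105), with Tbx1 marked and Myf5, Myog and Tnnc1 unmarked. The muscle call was absent in the own list of replicate 1, where 50% were marked. Cell types of the prominences were not separated, so an unmarked gene may still carry the mark in a minor cell type. Shares did not pass the test for facial epithelium (18 of 22, Irf6, Tfap2c and Pitx2 marked, Krt5 unmarked), cartilage and bone (13 of 21, Sox6 and Col2a1 marked, Matn1 and Col10a1 unmarked) and pigment and glia (10 of 16, Erbb3 and Kit marked, Tyr and Tyrp1 unmarked). They also did not pass for endothelium (12 of 20, Fli1 and Ets1 marked, Pecam1 and Cdh5 unmarked), heart (11 of 20, Myl3 and Hcn4 marked, Nkx2-5 and Myh6 unmarked), pluripotency (11 of 20, Klf4 and Sall4 marked, Pou5f1 and Nanog unmarked) and Hox genes (22 of 39, Hoxa1 and Hoxa2 marked, Hoxa3 and Hoxa6 unmarked).

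Against random lists matched on CpG count, the promoter calls of neural crest, jaw, signalling, nervous system, housekeeping, muscle, blood and lymphocyte genes were not past the threshold. Neural crest, signalling and housekeeping genes were at 100%, the highest possible share, against matched means of 91.1%, 93.3% and 90.7%. The matched test could therefore not have called these lists, and it does not show that CpG content accounts for their marking. Genes of like CpG count did share much of the excess over the 65.7% of all other genes. Jaw genes were at 95.2% against a matched 94.0%, nervous system genes at 91.3% against 86.3% and blood genes at 25% against 29.8%. Muscle genes were at 36.4% against a matched 48.4% and lymphocyte genes at 10% against 28.8%. Liver genes stayed below their matched lists, which averaged 28.1% (adjusted permutation p = 0.0018), germ cell genes below 64.5% (adjusted permutation p = 0.0012) and olfactory receptors below 6.63% (adjusted permutation p = 0.0012). Hox genes, at 56.4%, lay below a matched 89.1% (adjusted permutation p = 0.0012). The own lists gave 76.9% for Hox genes in replicate 1 and 51.3% in replicate 2 (64.1 ± 18.1, mean ± SD, n = 2).

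**Figure D2:**
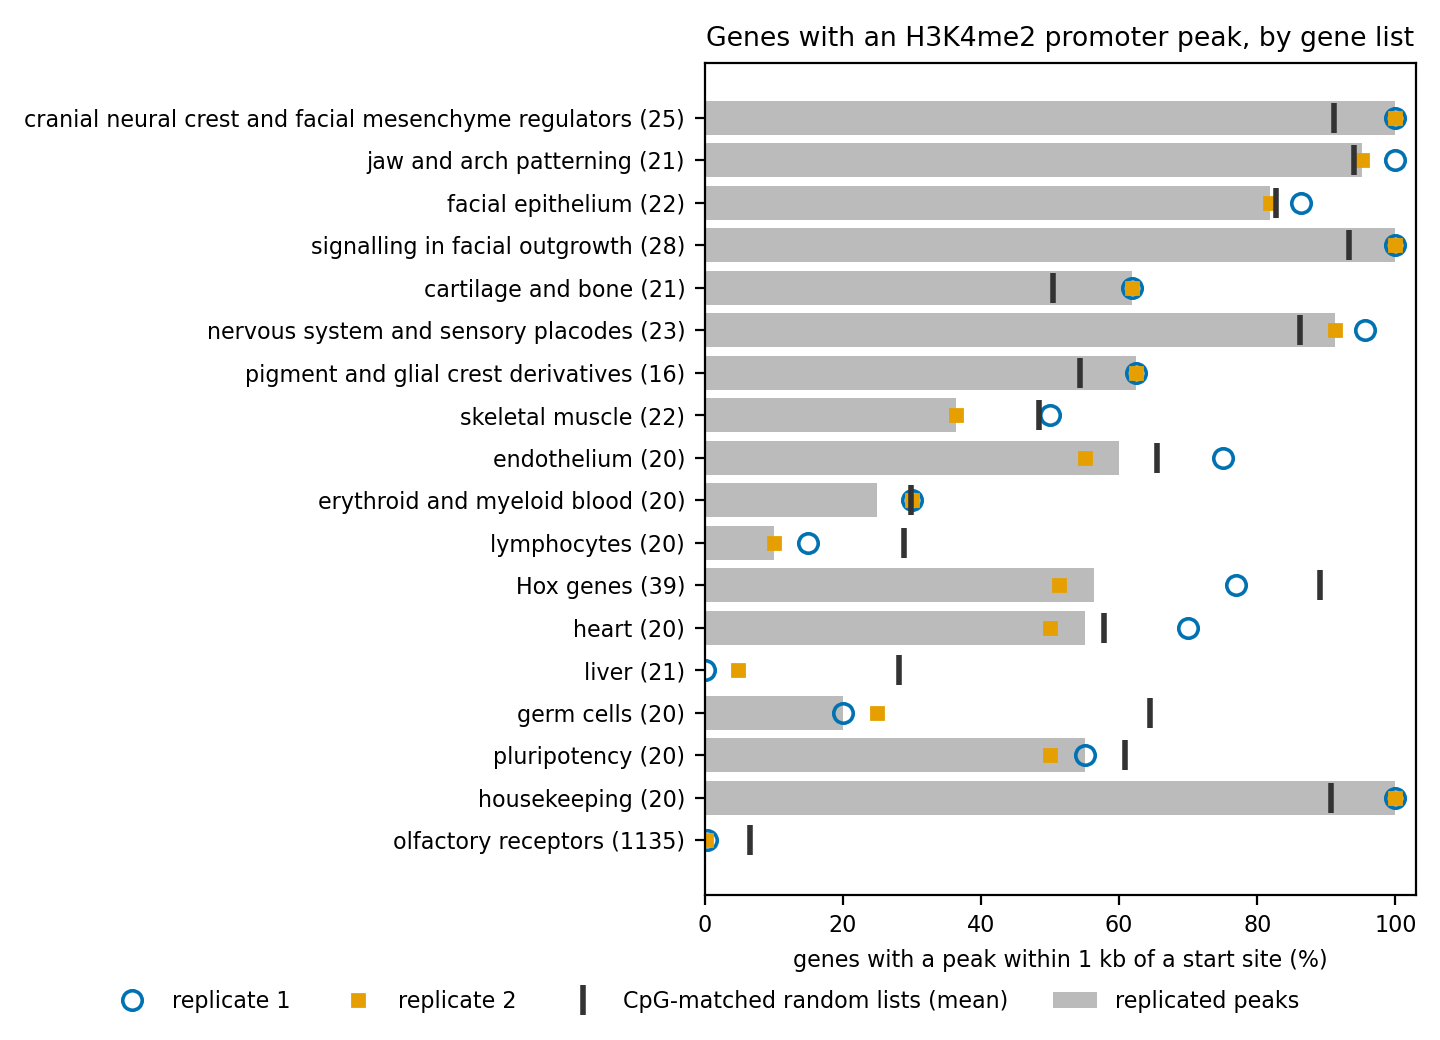
Share of genes (%) with a peak within 1 kb of a start site (horizontal axis) for each gene list (vertical axis, number of genes in brackets). Bars show replicated peaks, circles replicate 1, squares replicate 2 and vertical ticks the mean of CpG-matched random lists. Liver genes sit at 0% for replicated peaks and Hox genes at 56.4%, below their matched lists at 89.1%.

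The fifth comparison asked how broadly the mark covered each programme's start sites, out of 10 kb around the most covered start. In the neural crest and facial mesenchyme list, Six2, a regulator of palate and nasal mesenchyme, had 9649 bp covered (8862.5 ± 357.1 in the own lists, mean ± SD, n = 2). Meis2 had 9538 bp (9270.5 ± 513), Msx1 9400 bp (8835.5 ± 1249), Tfap2a 7570 bp (7154 ± 1397), Twist1 5989 bp (6005.5 ± 1392), Alx4 5818 bp (5635 ± 1328) and Sox9 5197 bp (5152.5 ± 653). In the jaw list, Nr2f1 had 9020 bp, Dlx1 7914 bp, Dlx5 5279 bp and Hand2 4846 bp, and among signalling genes Ptch1 had 9420 bp, Wnt5a 8592 bp and Shh 2136 bp. The median was 5818 bp for neural crest genes, 6162 bp for jaw and arch genes and 4620 bp for signalling genes, against a median of about 1350 bp in random lists (1352, 1349 and 1351 bp). Housekeeping genes (3257 bp, with 5331 bp at Tubb5) and nervous system genes (2607 bp, with 5327 bp at Six3 and 4558 bp at Pax6) were also broader than random lists. The adjusted permutation p was 0.0006 for each of these lists, and against CpG-matched lists it lay between 0.00072 and 0.0066.

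Facial epithelium did not stand apart, with a median of 1456 bp, although Tfap2c reached 5581 bp and Pitx2 4854 bp. Irf6 had 1676 bp and Trp63 0 bp. With cell types mixed, low values do not show how broad the mark is within a minor cell type. The differences between lists that follow were tested after the medians were seen. Neural crest genes exceeded facial epithelium by 4362 bp and jaw genes by 4706 bp in the median (permutation p = 1e-05 each, the smallest 100000 permutations can give, and 1.67e-05 adjusted over 5 such differences). The neural crest list holds transcription factor genes alone and the jaw list mostly such genes. Facial epithelium mixes them with keratin and adhesion genes. Kind of gene and tissue therefore cannot be told apart in these list medians. The 44 neural crest and jaw genes other than Edn1 and Ednra had a median of 6001.5 bp. Transcription factor genes of facial epithelium all lay below it: Trp63 (0 bp), Foxe1 (962), Ovol1 (1351), Grhl3 (1460), Irf6 (1676), Grhl2 (2186), Pitx2 (4854) and Tfap2c (5581). Tbx22 (1023 bp) and Hand1 (1508 bp) of the former lists were narrow too. This contrast, given without a test, argues against kind of gene as the whole cause. Neural crest genes exceeded nervous system genes by 3211 bp (permutation p = 2e-05, adjusted 2.5e-05) and Hox genes by 5258 bp (permutation p = 1e-05), and signalling genes exceeded housekeeping genes by 1363 bp (permutation p = 0.0139). Medians not past the threshold were 1331 bp for endothelium, 1294 bp for cartilage and bone, 1033.5 bp for pigment and glia, 605 bp for pluripotency, 560 bp for Hox genes, 523 bp for heart and 467 bp for muscle. The median was 0 bp for blood, lymphocyte, liver and germ cell genes, not past the threshold, and 0 bp for olfactory receptors (adjusted permutation p = 0.0006). The lowest possible median is 0 bp, so the blood, lymphocyte, liver and germ cell lists could not have passed this test as narrower. Single genes of the lists not past the threshold were broad, with 6337 bp at Fli1, 6213 bp at Hoxa2, 6107 bp at Sox6, 5820 bp at Tbx1, 5186 bp at Col2a1, 4732 bp at Klf4 and 4683 bp at Runx1. Against CpG-matched lists, Hox genes (matched median 1676 bp, adjusted permutation p = 0.00072) and germ cell genes (1187 bp, adjusted permutation p = 0.0211) were narrower. The call for olfactory receptors ended there, as their matched median was also 0 bp. Windows can hold peaks of neighbouring genes. Cd68, Tnp2, Tnnc1 and Apoa2 had 2960, 2654, 2424 and 1439 bp covered without a replicated promoter peak. Which genes those peaks belong to was not determined.

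**Figure D3:**
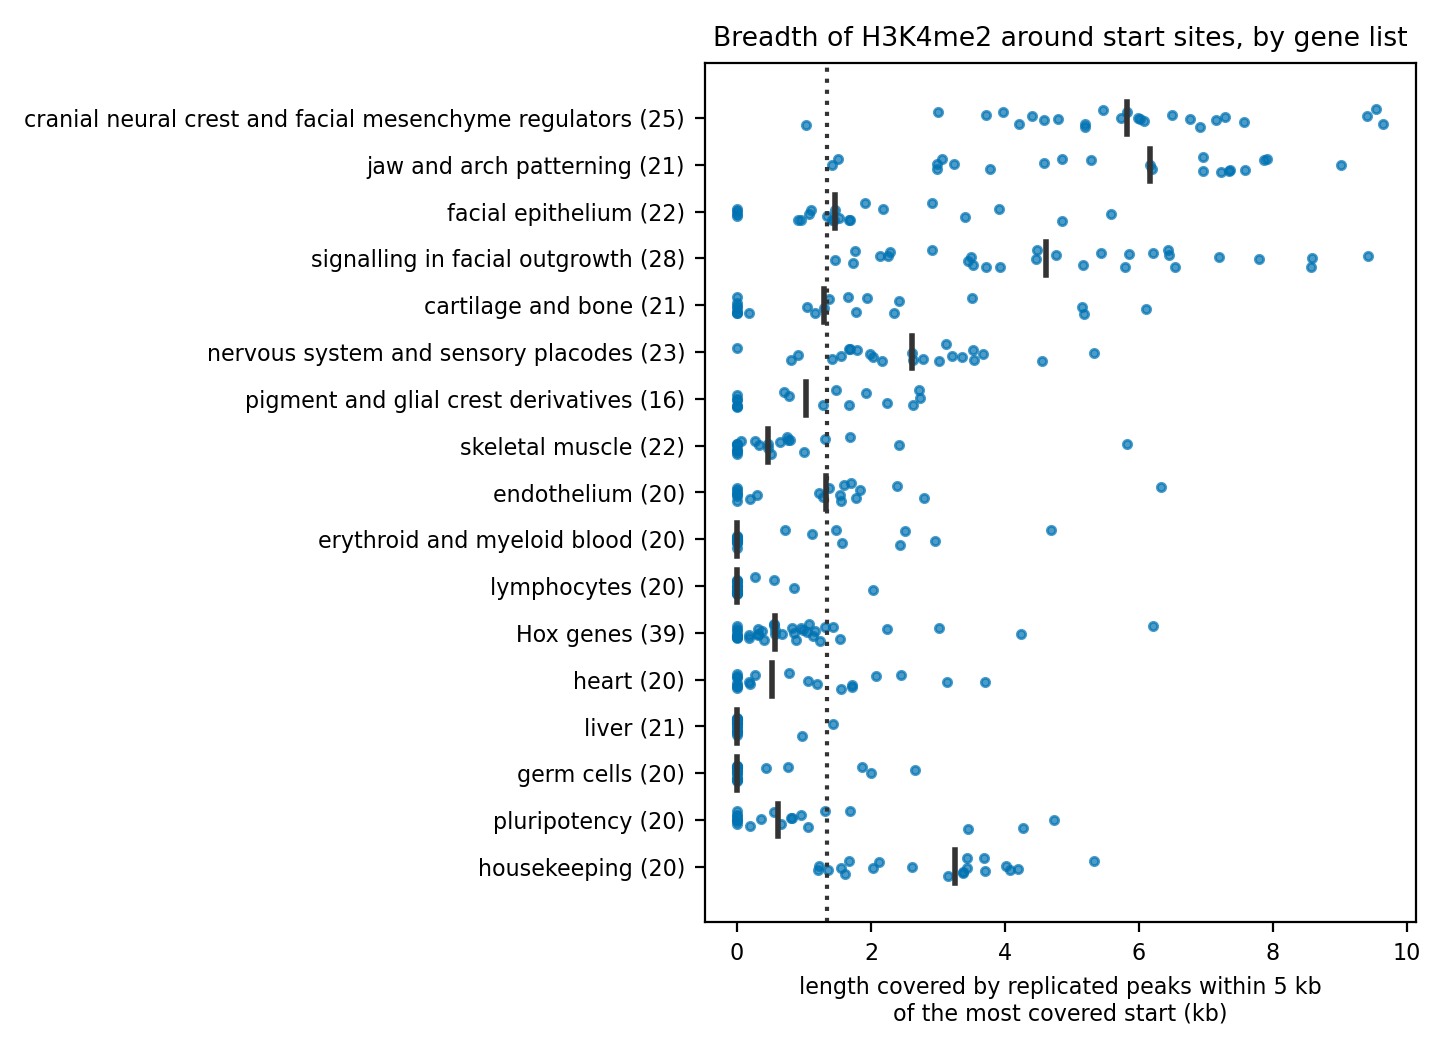
Length covered by replicated peaks within 5 kb of the most covered start (kb, horizontal axis) for each gene (points) of each list (vertical axis, number of genes in brackets). Vertical bars are list medians and the dotted line the median of random lists of 20 genes (1342 bp). Neural crest (5818 bp), jaw (6162 bp) and signalling (4620 bp) medians lie to the right of the line.

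The sixth comparison asked which genes had distal peaks, in sequence where enhancers are found, nearby. Meis2 had 13 distal replicated peaks, Nr2f1 11, Tfap2a 10, Hand2 9, Six2 and Twist1 8 each, Ptch1 7 and Msx1, Alx4 and Sox9 5 each. Shh and Dlx5 had 2, Irf6 1, and Trp63, Alb and Gata1 0. Some of these peaks were parts of the broad domain around the start: outside merged domains that reached within 2.5 kb of a start, Twist1 and Dlx5 had 0, Ptch1 1, Six2 2, Msx1 and Sox9 3, Meis2 9 and Nr2f1 10, while Tfap2a, Hand2 and Alx4 kept 10, 9 and 5. Counts at several of these genes differed over 1.5-fold between lists. In the own lists of replicates 1 and 2 they were 17 and 10 at Nr2f1, 17 and 12 at Hand2, 15 and 11 at Six2, 7 and 13 at Msx1, 4 and 3 at Shh, 3 and 8 at Dlx5, 2 and 1 at Irf6 and 1 and 0 at Trp63. Genome wide, the most distal peaks were assigned to Gse1 (24), Cstad (19), Bcor (18), Zfhx3 (16, of which 12 lay outside such domains) and 1700001O22Rik (15). The own lists gave 64 and 25 at Gse1, 26 and 16 at Cstad, 35 and 23 at Zfhx3 and 24 and 13 at 1700001O22Rik. The assignment is to the nearest start and does not show which gene a peak regulates. Starts of noncoding genes were not considered in these counts, so some distal peaks may lie at promoters of such genes. In total 7674 distal peaks were assigned to 4113 genes (18.7%), a mean of 0.35 per gene, and 39 genes had 10 or more. Of the assigned peaks, 587 (7.65%) lay in such a domain around a start.

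Neural crest genes had 5.04 distal peaks per gene, jaw genes 4.0, signalling genes 2.36 and nervous system genes 1.91, against 0.351 to 0.352 in random lists. The adjusted permutation p was 0.0009 for the first 3 lists and 0.00144 for nervous system genes. Random lists matched on the length of sequence nearest to the gene averaged 0.574, 0.562, 0.634 and 0.573, and all 4 calls held against them (adjusted permutation p = 0.0009, 0.0009, 0.0009 and 0.00648). Without peaks in domains around a start, an alternative chosen after the data were examined, neural crest genes had 3.12, jaw genes 2.67, signalling genes 1.79 and nervous system genes 1.83, and these calls held (adjusted permutation p = 0.0009, 0.0009, 0.0009 and 0.00144). In the own lists, neural crest genes had 6.64 ± 1.19, jaw genes 6.05 ± 1.89, signalling genes 3.84 ± 1.14 and nervous system genes 3.04 ± 0.799 distal peaks (mean ± SD, n = 2). The longer list of replicate 1 alone gave 7.38 for jaw, 4.64 for signalling, 3.61 for nervous system and 2.24 for cartilage and bone genes. Cartilage and bone genes had 1.33 (adjusted permutation p = 0.021), a call absent in the own list of replicate 2 (1.19) and against matched lists. Olfactory receptors had 0.0211, below random lists (adjusted permutation p = 0.0009). The remaining 12 lists were not past the threshold, with means from 0.19 for liver to 0.955 for facial epithelium.

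The seventh comparison ranked loci by the span of merged peaks, without choosing genes beforehand. The widest domain spanned 24980 bp at Nr2f2, a nuclear receptor gene, on chromosome 7 from 70345885 to 70370864. Ebf3 followed with 21981 bp and Tbx2 with 16574 bp, the latter a single peak on chromosome 11 from 85828621 to 85845194. Ptch1, the Hedgehog receptor gene, spanned 16025 bp, Tbx3 15989 bp, Bahcc1 15949 bp, Nr2f1 15894 bp, Zfp503 14521 bp, Irx5 14270 bp and Twist1 13972 bp. The own lists covered 21268.5 ± 2368 bp of the Nr2f2 domain, 15968 ± 857 bp of the Tbx2 domain and 10587.5 ± 2224 bp of the Twist1 domain (mean ± SD, n = 2). There were 21968 merged domains with a median span of 1318.5 bp.

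The 500 widest domains, each of at least 4731 bp, held starts of 559 genes. Among neural crest and facial mesenchyme genes 18 of 25 (72%) were in these domains, against 2.47% of other genes (adjusted Fisher's exact p = 1.15e-22). Jaw and arch genes were in them in 13 of 21 cases (61.9%, adjusted exact p = 2.53e-15) and signalling genes in 13 of 28 (46.4%, adjusted exact p = 2.63e-13). The own lists gave 74.0 ± 14.1% for neural crest, 59.5 ± 10.1% for jaw and 48.2 ± 2.53% for signalling genes (mean ± SD, n = 2). Olfactory receptors were in them in 0 of 1135 cases (adjusted Fisher's exact p = 8.23e-13). Cartilage and bone (3 of 21, adjusted exact p = 0.056), facial epithelium (2 of 22), nervous system (2 of 23), housekeeping (2 of 20), pluripotency (2 of 20), Hox (2 of 39), endothelium (1 of 20) and blood (1 of 20) genes did not pass the test. Pigment and glia, muscle, lymphocyte, heart, liver and germ cell genes had 0 members in these domains and did not pass either. With about 2.55% of other genes in the domains, lists of this size could not have passed as depleted.

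**Figure D4:**
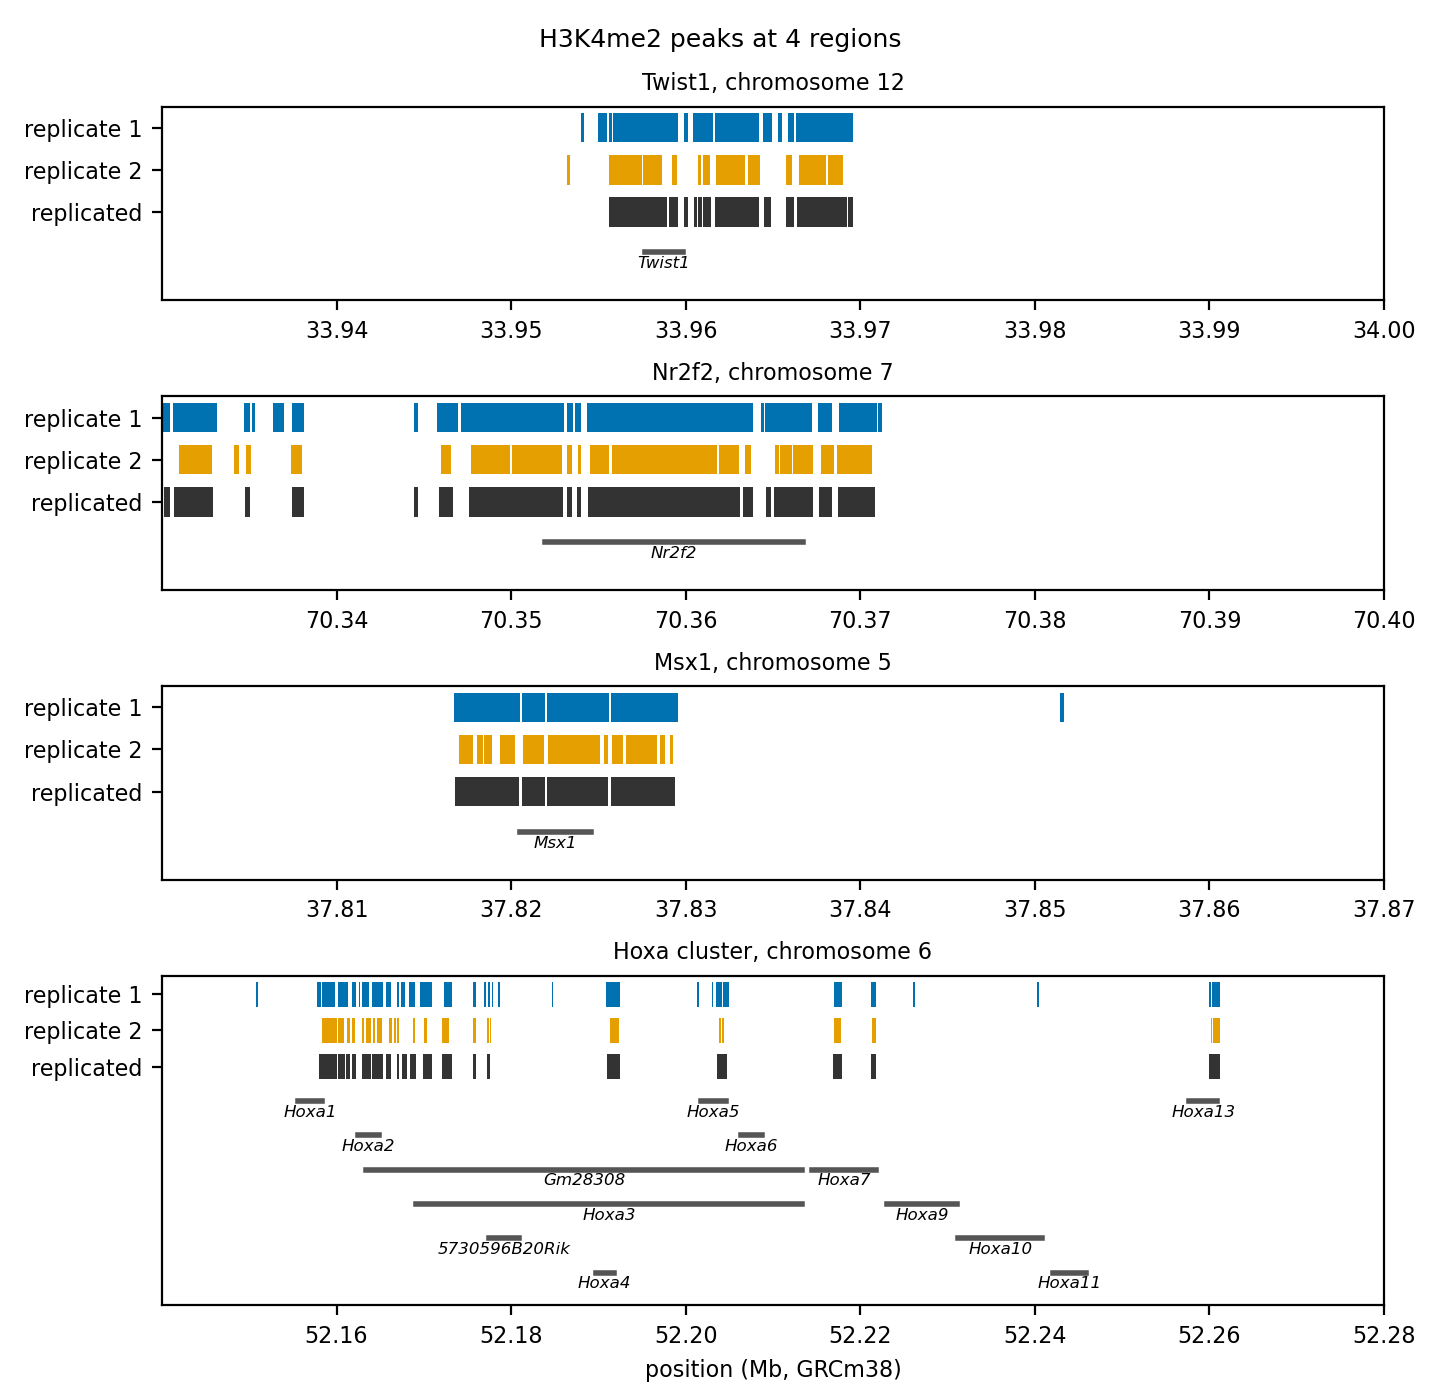
Peaks of replicate 1, replicate 2 and the replicated list (rows of boxes) and protein-coding genes (lines) at Twist1, Nr2f2, Msx1 and the Hoxa cluster, with position in Mb on GRCm38 (horizontal axis). Peaks cover most of the 13972 bp domain at Twist1 and the 24980 bp domain at Nr2f2, while peaks in the Hoxa cluster are densest around Hoxa1 and Hoxa2.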

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

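Both counts below were made after the peak lists had been examined. Peaks on unplaced contigs entered no comparison with genes, but 10 replicated peaks lay on 4 such contigs, a signal in sequence left out of the tests. Their number was not compared with an expected one. Of the 10 peaks, 8 overlapped a peak of both own lists. Their median enrichment was 5.1, their highest enrichment 7.55 and their median width 378.5 bp. No technical or biological explanation was tested for them.

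Peaks shared by both own lists but absent from the pooled list were also counted, and 36 of the 26639 shared peaks of replicate 1 (0.135%) overlapped no pooled peak. They were narrow, with a median width of 199 bp and a median enrichment of 2.88 in the list of replicate 1. The tests on replicated peaks therefore did not include them, and no explanation was tested for them.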

How the results depend on the processing

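The alternatives with replicated peaks found in both own lists and with distal peaks outside domains around a start were chosen after the data were examined. The former changed no direction or call, with promoters holding 70.2% of those peaks, and the latter ended no call and switched the side of distal Hox values alone (0.205). The overlap of the replicates and the promoter share of peaks kept their direction and call under every alternative run. Breadth calls of neural crest, jaw, signalling, nervous system and housekeeping genes, distal calls of the first 4 of these lists and domain calls of neural crest, jaw and signalling genes also held under every alternative run. The values below belong to list results that crossed a threshold, or whose side of the background switched; most of the latter were never past the threshold. The cause was not tested unless stated.

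Against CpG-matched lists the values stay as reported and only the background moves. Promoter calls ended for neural crest (100%), signalling (100%), housekeeping (100%), jaw (95.2%), nervous system (91.3%), muscle (36.4%), blood (25%) and lymphocyte genes (10%). The lists at 100% could not have passed the matched test, so their ended calls do not show that CpG content accounts for the marking. The call for Hox genes (56.4%) appeared, and facial epithelium (81.8%), cartilage (61.9%) and pigment genes (62.5%) switched side. Breadth calls appeared for Hox (560 bp) and germ cell genes (0 bp), ended for olfactory receptors (0 bp), and switched side for facial epithelium (1456 bp), endothelium (1331 bp), cartilage (1294 bp), pigment (1033.5 bp) and muscle (467 bp). Against lists matched on nearby sequence length, the distal call of cartilage genes (1.33) ended and blood and lymphocyte genes (0.25 each) switched side.

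With −log10 q of at least 5, promoter calls appeared for Hox (43.6%) and pluripotency genes (40%), and distal Hox (0.205), distal blood (0.25) and widest-domain nervous system values (0%) switched side. With pooled peaks, promoters of heart genes (70%), breadth of cartilage genes (1368 bp) and distal peaks of Hox (0.385) and blood genes (0.45) switched side, and a distal call appeared for facial epithelium (1.5). Taking only the 5′-most start gave a promoter call for pluripotency genes (35%), a promoter window of 500 bp one for Hox genes (46.2%), and a window of 2 kb ended that of muscle (45.5%). A breadth window of 2 kb switched facial epithelium (1160 bp). Among marked genes alone, breadth calls appeared for Hox (1009.5 bp), pluripotency (1063 bp) and muscle (883.5 bp), and cartilage (1938 bp), blood (2441 bp) and facial epithelium (1602.5 bp) switched side. Assignment within 50 kb ended the distal call of cartilage (0.857). Distal Hox values switched side beyond 5 kb (0.128) and after merging across 1 kb (0.256).

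For the widest domains, a merging gap of 3 kb gave a call for nervous system genes (21.7%) and switched blood (0%) and muscle (4.55%). No merging switched Hox, endothelium, blood, housekeeping and nervous system genes (0% each) and heart (5%). The widest 1000 domains switched endothelium and blood (5% each). With each replicate's own list in place of the replicated list, promoter shares ranged from 51.3% to 76.9% for Hox, 55% to 75% for endothelium, 50% to 70% for heart and 36.4% to 50% for muscle. Breadth ranged from 1279 to 1457 bp for cartilage and from 1092 to 1543 bp for endothelium. Distal peaks ranged from 0.359 to 0.564 for Hox, 1.19 to 2.24 for cartilage and 0.3 to 0.95 for blood, and widest-domain shares from 0% to 13.0% for nervous system and 5% to 15% for housekeeping genes. Read depth, which limits how many weak peaks can be called, is unknown.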

Other observations

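Families of genes, and tests of CpG content, of position within Hox clusters and of gene lists among promoters marked in replicate 1 alone, were chosen after the related values were seen; the other tests were fixed before their results. The 18 families were picked by symbol with the widest domains in view, so their counts in the 500 widest domains are descriptive and carry no p-value. Ebf1, Ebf2 and Ebf3 (3 of 4 Ebf genes) and Id1, Id2 and Id3 (3 of 4 Id genes) lay in these domains, as did Irx2, Irx3 and Irx5 and Six1, Six2 and Six5 (3 of 6 genes in each family). So did Hes1, Hes5, Hes7 and Hey1 (4 of 9 Hes and Hey genes), Nr2f1 and Nr2f2 (2 of 3), Sox4, Sox6, Sox9 and Sox12 (4 of 19) and 9 of 44 Fox genes, Foxc1, Foxc2, Foxf1 and Foxp1 among them. The counts were 2 of 13 for Tbx, 2 of 11 for Bmp, 2 of 19 for Wnt, 2 of 22 for Fgf, 11 of 365 for Zfp, 4 of 72 for ribosomal protein and 1 of 44 for collagen genes. They were 0 of 5 for Zic, 0 of 49 for keratin and 0 of 327 for vomeronasal receptor genes. All 72 ribosomal protein genes and all 19 Sox genes carried a replicated promoter peak, against 9 of 49 keratin genes (18.4%).

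Six2, Meis2, Msx1 and the other facial mesenchyme and jaw regulators had broad marking, with a median of 5903.5 bp over 46 genes. CpG-matched lists had 1787.5 bp (permutation p = 0.0002), which argues against CpG count near the 5′-most start as the whole cause. Matching was by 10 bins of CpG count, so differences within a bin remained. Lists were not matched on CpG content further out in the window, so its part in the breadth stays open. The 45 members without another protein-coding start within 10 kb had a median of 5818 bp, against 1164 bp for random genes of that kind (permutation p = 0.0002), which argues against peaks of neighbouring genes. Without Edn1 and Ednra, 44 of the 46 genes remained, all transcription factor genes apart from the coactivator gene Eya1. These 44 exceeded 51 transcription factor genes of nervous, muscle, heart, blood, endothelium, liver and pluripotency lists by 4329.5 bp in the median (6001.5 against 1672 bp, permutation p = 1e-05, the smallest possible). Those other factors ranged in median from 0 bp for liver (2 genes) and 468 bp for muscle (7 genes) to 2783 bp for nervous system (15 genes). Transcription factor genes of facial epithelium were not among them. Whether stronger immunoprecipitation alone widens called peaks was not tested.

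Hox promoters carried a replicated peak less often than promoters of like CpG count, by −32.7 percentage points (adjusted permutation p = 0.0012). This difference defines the pattern, so it is no separate test of CpG content, and against all other genes the share (56.4% against 65.7%) was not past the threshold (adjusted Fisher's exact p = 0.33). In the longer own list of replicate 1 the share was 76.9%, still below a matched 90.3% (permutation p = 0.0048). In replicate 2 the share was 51.3% against 88.6%, so the gap was smaller in the longer list. Every list ends at a calling threshold, so the gap that remained in replicate 1 does not exclude a loss of weak peaks at that threshold, which stays open. Paralogue number and covered base pairs had a mean Spearman correlation within the 4 clusters of −0.475, and of −0.475 and −0.588 in the own lists of replicates 1 and 2. The correlation was negative in 4 of 4 clusters. Neighbouring Hox genes share peaks, as Hoxb5 and Hoxb6 (308 bp each) do, so clusters and not genes are the independent units, and 4 clusters cannot give an exact one-sided sign test below p = 0.0625. The 8 genes of paralogue groups up to 3 had a median of 1700.5 bp with 6 marked, and the 16 genes of groups 9 and above had 243.5 bp with 6 marked. The own lists of replicates 1 and 2 marked 8 and 6 of the former and 11 and 5 of the latter. Marking that declines along the clusters therefore stays an open hypothesis.

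Promoters of 477 genes were marked in replicate 1 alone, and these included 10 of the 19 Hox genes unmarked in replicate 2 (adjusted one-sided Fisher's exact p = 5.71e-07, too small because Hox neighbours share peaks). They also included Eng, Plvap, Robo4 and Mmrn2 of endothelium (4 of 9, adjusted exact p = 0.00897) and Nppb, Tbx5, Myh7 and Nkx2-5 of heart (4 of 10, adjusted exact p = 0.00948), against 6.23% of other such genes. The other such genes were not matched on CpG count. They included 1133 olfactory receptor genes, of which 0.177% were marked in replicate 1, so the share they give is a low baseline. No other list of 12 tested passed. The median rank of the best peak at the 477 promoters was 70.4% from the top of the list, against 15.6% at promoters marked in both. These promoters were chosen for lacking a peak in replicate 2 and weak peaks were seldom shared, so a low rank was built in, and a small share of another tissue would also give weak peaks. Weak peaks near the calling threshold and another tissue in replicate 1 cannot be told apart. Of 69 effector genes of heart, muscle, blood, lymphocytes and liver unmarked in replicate 2, 5 (7.25%) were marked in replicate 1, against 6.26% of other genes (one-sided Fisher's exact p = 0.437), too few to decide.

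A paired motif of the E-box CAGATG and TAATT at a fixed spacing, the arrangement bound jointly by TWIST1 and homeodomain factors, was sought in 8664 distal peaks and in flanking sequence 10 kb away. Of 64 orientations and spacings up to 15 bp, 0 were more frequent in peaks by at least 1.5-fold with an adjusted Fisher's p past the threshold. At an unadjusted p under 0.05 there were 3, of which 0 were more frequent in peaks. No pair occurred in more than 6 peaks. At the median of 3 flanks with a pair, a single pair needed 20 peaks to pass, so even an enrichment of several fold was not detectable and the motif stays open. Distal peaks had a GC content of 54.8%, against 45.6% in flanks, and flanks were not matched on it. TAATT alone occurred in 40.6% of peaks and 52.5% of flanks, CAGATG in 32.6% and 36.5%, and the E-box CAGCTG in 35.4% and 23.9%. The 32 orientations and spacings tried with CAGCTG gave 0 passing pairs as well.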
